A study of Mus musculus with 125 samples.

How the data were processed

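The series holds 125 ChIP-seq and input libraries in 31 groups. Most come from forebrain (cortex and hippocampus) of male C57BL/6 mice. One cohort compares wild-type (WT) mice with MeCP2 knockout (KO) mice at 8 weeks. Another compares WT mice with mice carrying R306C, a missense allele of MeCP2 in the domain that contacts the NCoR/SMRT co-repressor, at 8 to 12 weeks. WT libraries of H3K79me2, and libraries of the transcription factor YY1 from cultured cortical neurons taken at embryonic day 16.5, complete the series. Per the labels' protocols, tissue was flash frozen, cross-linked in formaldehyde and sonicated, and chromatin was immunoprecipitated with antibody-coated beads. The labels do not say that replicates of a group are separate animals, so p-values measure the spread between these samples, which may be technical.

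Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and aligned to the mouse genome build mm10 with Bowtie2 2.2.9, and SAMtools 0.1.19 and bedtools (no version given) were also used. Down-sampling and duplicate removal are not stated. The 9 count tables deposited by the authors hold whole-number read counts per gene and library, with no normalisation stated. Per the file headers, each gene comes with its chromosome, start, stop and strand. H3K36me3 and H3K79me2 counts cover whole genes (24498 genes). Pol II counts cover the 2000 bp window centred on the transcription start site (TSS) of the same 24498 genes. H3K27ac, H3K9ac and H4K12ac counts were deposited both for that TSS window and for the gene body from 3 kb after the TSS to the gene end, and MeCP2 counts for the latter region, each for 17929 genes that span at least 4500 bp. The deposited YY1 file is of another kind: per its file name it lists positions of YY1 motif instances within YY1 peaks of neurons at 0 and 6 h of KCl, with no counts. Peak lists, alignments and the YY1 read counts are not held here and were not analysed.

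Every per-sample column was assigned to a sample from its title, and 0 columns stayed unassigned. For H3K27ac of the R306C cohort the column numbers (4 and 5) do not match the sample titles, so these columns were grouped by genotype and antibody only. Gene spans were taken from the tables, and 23533 of the 24498 symbols were found in the RefSeq gene table while 965 were not.

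Each comparison of genotypes was fitted in edgeR 4.0.16 under R 4.3.3 with TMM factors, the default expression filter, quasi-likelihood F-tests and genotype as the only term. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested in that comparison. Log2 fold changes are mutant over WT, given with their standard error (SE), and gene levels are CPM, counts scaled by the library total within the counted regions to a common size, with the standard deviation (SD) over replicates. That total was multiplied by the TMM factor for the levels beside fold changes. It was left plain for the levels of Mecp2, the length contrasts, the levels of marker lists, the H3K79me2 and MeCP2 signals over input, the figure of 4933407K13Rik and the libraries that stood apart in single genes. The 20 gene lists, holding 674 genes, were written from general knowledge before the data were examined, as were the comparisons, the tests and the rule for naming genes. They are activity-induced genes, astrocyte, oligodendrocyte lineage, microglia, endothelial and pericyte, excitatory neuron and inhibitory neuron markers, cytosolic ribosomal protein genes, glucocorticoid-response genes, Hox and other silenced developmental genes, imprinted genes, ion channels, neurotransmitter receptors, liver, muscle and blood genes, the MeCP2 and NCoR co-repressor complex, MeCP2-linked genes in earlier literature, oxidative phosphorylation, the proteasome, synaptic adhesion and axon guidance, and synaptic vesicle and presynaptic release. Of these genes, 10 stand in more than 1 list. Lists were tested with camera in limma 3.58.1 at the preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and again with the correlation estimated from the data. No list test held a term for gene length, so a list of mostly long or short genes can pass through a length trend alone. Counts of called members are given over all genes tested and adjusted over the list alone.

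The length contrast of a library is the mean log2 CPM (prior count 2) of tested genes longer than 100 kb minus that of tested genes of 100 kb or less. Groups were compared by a two-sided permutation test with 1e+05 resamples for groups of 10 and by exact enumeration for smaller groups. With 2 libraries per group such a test cannot go below 0.333, with 3 per group below 0.1, with 4 below 0.0286 and with 5 below 0.00794. Fold changes of comparisons that share no library were compared by Spearman correlation across genes against 100 redrawn genotype assignments where that many exist, with adjustment over the 74 pairs. H3K36me3 and H3K27ac libraries of the KO cohort may come from the same animals. Differences between the KO and R306C effects were tested as an interaction in edgeR. ChIP libraries were set against inputs of the same table, with library totals as the scale, for H3K79me2 and MeCP2.

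Genes named for a comparison are Mecp2, the 8 called genes with the largest change in each direction among those with a mean count of at least 50, the members with the smallest p of each list past 0.05, and members of the MeCP2-linked and synaptic adhesion lists in any case. Where 0 genes were called, the 4 with the smallest p in each direction were considered, and these are described as not passing. Genes outside this rule that the text names, because they moved against their list or were raised by another check, were chosen after their values were seen. They are Nrxn2, Ptprf and Slc17a6 for H3K36me3, Ptprs, Plxna2, Lingo2, Cdh9, Ncam1, Nfasc, Il1rapl2, Mbp and Sox10 for H3K27ac, and 4933407K13Rik in input libraries.

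Alternatives covered total-count scaling, DESeq2 1.42.0 size factors, the DESeq2 Wald test, no expression filter, a joint fit of ChIP and input libraries that tests the genotype effect beyond the input, a block for the replicate number, and each library left out in turn where groups held 5 or fewer. For the length contrast they covered a threshold of 60 kb, prior count 10, medians, active genes only, input subtraction and a block for the replicate number. After the data were examined, fits without WT libraries 4 and 5, and without WT libraries 6 and 9, of the KO cohort were added because these libraries stood apart. The calculations were tested on simulated data made from each comparison's own counts, with 200 changed genes. At log2 0.5 the tests recovered 100% of changed genes for H3K36me3 and for both H3K27ac regions in KO, 83.6% for Pol II in KO, 95.5% for H3K9ac at the TSS, 86.6% for H3K9ac in gene bodies, 62.7% and 65.7% for H4K12ac, 59.7% and 29.9% for H3K27ac in R306C, 23.9% for Pol II in R306C, 16.4% for Ser5p and 80.6% for MeCP2. Between 3.96% and 9.21% of simulated calls were false. Changed genes were drawn among those with a mean count of at least 50, so recovery at lower counts was not measured. Simulated counts were independent and held no structure shared by libraries. Rates in the real libraries may therefore be worse.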

Results

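Histone marks of transcription and acetylation, RNA polymerase II (Pol II) and MeCP2 itself were profiled by ChIP-seq in mouse forebrain with and without a functional MeCP2, the methyl-DNA binding protein whose loss causes Rett syndrome. The KO cohort held 10 WT and 10 KO libraries each of H3K36me3, a mark laid down in gene bodies during elongation, of H3K27ac, a mark of active promoters and enhancers, and of input, and 2 WT and 2 KO libraries each of Pol II and its input. The R306C cohort held per genotype 5 libraries of H3K9ac, 3 of H4K12ac, 2 of H3K27ac, 4 of MeCP2, 2 of Pol II, 2 of Pol II phosphorylated on serine 5 of its C-terminal repeats (Ser5p), and inputs of these. WT forebrain gave 2 libraries of H3K79me2 with 2 inputs. YY1 libraries (1 at 0 h and 1 at 6 h of KCl, and 1 input) have no replicates, and only a list of motif positions was deposited for them.

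Depth is given as megacounts per library within the counted regions. In the KO cohort, H3K36me3 libraries held 9.37 to 9.79 (WT) and 9.43 to 10.0 (KO), H3K27ac libraries 2.503 to 3.15 and 2.63 to 2.95 at the TSS and 10.8 to 11.2 and 11.2 to 11.4 in gene bodies, and Pol II libraries 2.98 to 3.20. Inputs of the histone marks of that cohort held 6.17 to 6.63 over whole genes but 0.323 to 0.430 in TSS windows, and its Pol II inputs 0.507 to 0.545. In the R306C cohort, TSS totals were 3.47 to 4.62 for H3K9ac, 0.932 to 1.38 for H4K12ac, 2.45 to 3.04 for H3K27ac, 2.21 to 2.95 for Pol II and 1.03 to 1.39 for Ser5p, 0.380 to 0.463 for the inputs of the histone marks and 0.481 to 0.548 for those of Pol II. Gene body totals were 8.65 to 9.08 for H3K9ac, 9.34 to 10.3 for H4K12ac, 10.98 to 11.3 for H3K27ac and 7.43 to 7.98 for MeCP2. H3K79me2 libraries held 24.9 to 25.6.

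Mecp2 (chromosome X, 74026592 to 74085690, minus strand) carried less H3K36me3 in KO. Its level was 50.2 ± 2.32 CPM in WT and 38.9 ± 2.48 in KO (SD, n = 10 each), and the WT range of 45.5 to 53.3 did not overlap the KO range of 34.7 to 43.4. Input libraries read 37.4 ± 3.03 and 36.1 ± 2.62 CPM over the gene (SD, n = 10 each). The KO share of reads thus lay near that of input. That is not a background level, since each is scaled to its own library total. The log2 fold change was -0.35 ± 0.04 (SE, adjusted p = 2.78e-08). Other tables showed 0 calls for Mecp2 in edgeR. Its H3K27ac levels in WT and KO were 78.7 ± 6.56 and 76.1 ± 3.99 CPM at the TSS and 34.5 ± 1.79 and 32.6 ± 2.01 in the body (SD, n = 10), and its Pol II levels were 91.7 ± 1.75 and 96.2 ± 12.6 CPM (SD, n = 2). In R306C against WT, H3K9ac at the Mecp2 TSS read 82.2 ± 3.43 against 78.2 ± 4.00 CPM (SD, n = 5), H4K12ac 71.6 ± 5.07 against 57.8 ± 7.88 (n = 3), H3K27ac 83.8 ± 4.94 against 83.4 ± 2.65 (n = 2), Pol II 101 ± 0.778 against 90.4 ± 5.52 (n = 2) and Ser5p 82.0 ± 15.3 against 95.1 ± 15.9 (n = 2).

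The KO cohort asks how gene body and promoter chromatin differ when MeCP2 is absent. In H3K36me3, Tenm3, a teneurin that joins partner cells at synapses (chromosome 8, 48225665 to 48674690), rose from 289 to 355 CPM (log2 0.29 ± 0.03 SE, adjusted p = 2.66e-10, n = 10 per group). Bmper, a secreted regulator of bone morphogenetic protein signalling (chromosome 9, 23223076 to 23485215), rose from 154 to 201 CPM (log2 0.39 ± 0.03, adjusted p = 6.15e-12). The largest named falls were in Col11a2, a fibrillar collagen (log2 -0.51), the zinc finger gene Zfp616 (-0.49), Nlrp4f (-0.47), Fxyd7, a regulator of the sodium pump (-0.46), and Pcbp4, an RNA-binding protein gene (-0.42). In all, 1483 of 19799 genes tested were called, 932 up and 551 down, with a median size of log2 0.16.

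Synaptic adhesion and axon guidance genes carried the clearest group gain of H3K36me3, with 37 up and 2 down of 73 tested (49 up and 3 down adjusted over the list alone; median log2 0.10, adjusted p = 7.02e-26, but adjusted p = 0.305 with an estimated correlation). The guidance genes Sema5a (log2 0.22), Slit1 (0.23) and Slit3 (0.17) were among those that rose, and the 2 that fell were Nrxn2, a presynaptic neurexin (-0.16), and Ptprf, a receptor phosphatase (-0.10). Ion channel genes had 14 up and 0 down of 43 (21 and 2 adjusted over the list alone, adjusted p = 1.83e-08, and adjusted p = 0.465 with an estimated correlation). Among them were the calcium channel subunit gene Cacna2d3 (log2 0.17) and the potassium channel genes Kcnd2 (0.17) and Kcnh5 (0.16). Neurotransmitter receptor genes had 11 up and 0 down of 43 (18 and 1 adjusted over the list alone, adjusted p = 6.15e-07, and adjusted p = 0.465 with an estimated correlation). Among them were the kainate receptor gene Grik4 (log2 0.18) and the dopamine receptor gene Drd2 (0.22). Excitatory neuron markers had 5 up of 21 (7 adjusted over the list alone, adjusted p = 0.000254, and adjusted p = 0.318 with an estimated correlation). These were the transcription factor genes Cux1, Cux2, Bcl11b and Rorb and the vesicular glutamate transporter gene Slc17a6. H3K36me3 changes also rose with gene length, which the list tests did not take into account. Gains of these lists were therefore not told apart from that trend.

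MeCP2-linked genes from earlier literature had 4 up of 18 in H3K36me3 (5 adjusted over the list alone, adjusted p = 0.0043, and adjusted p = 0.305 with an estimated correlation). Those were Fkbp5, a stress-induced chaperone of the glucocorticoid receptor (chromosome 17, 28398753 to 28486149; log2 0.31 ± 0.04, adjusted p = 1.45e-07), Sgk1, a glucocorticoid-induced kinase (0.19), Rbfox1, a neuronal splicing factor (0.13), and Irak1, an innate immune kinase that neighbours Mecp2 (0.22). Imprinted genes had 2 up of 23, Rasgrf1 (0.10) and Sgce (0.09), with a list adjusted p = 0.0219 (2 adjusted over the list alone, and adjusted p = 0.317 with an estimated correlation). The MeCP2 and NCoR complex list had 2 down of 20, which were Mecp2 itself and the co-repressor gene Ncor2 (log2 -0.09, adjusted p = 0.0409), with a list adjusted p = 0.0281 (2 down adjusted over the list alone, and adjusted p = 0.305 with an estimated correlation). Ribosomal protein genes (median log2 -0.03, adjusted p = 0.0569) and proteasome genes (median -0.03, adjusted p = 0.118) did not pass, and the proteasome list passed in 0 of the 13 comparisons. Oligodendrocyte markers had a median of -0.09 (adjusted p = 0.0787), astrocyte markers -0.02 (0.715), microglia markers -0.02 (0.841) and endothelial markers 0.04 (0.218). The mean level of oligodendrocyte markers per library was nevertheless lower in KO, at 3.87 ± 0.07 log2 CPM in WT and 3.75 ± 0.08 in KO (SD, n = 10 each, permutation p = 0.0025, 0 of 10 KO libraries above the WT median).

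4933407K13Rik, a locus of unassigned function on chromosome X (75725458 to 75764699), had the largest named gain of H3K36me3, from 38.4 to 55.3 CPM (log2 0.52 ± 0.04 SE, n = 10 per group), but it was also higher in KO input DNA (log2 0.69). When ChIP and input libraries were fitted together, 274 genes were called beyond the input (214 up, 60 down), 4933407K13Rik turned to -0.16 and Irak1 to -0.03, and Zfp616, Drd2, Sgk1, Rbfox1, Cux1, Cux2, Bcl11b, Rorb, Rasgrf1, Sgce and Ncor2 no longer passed. Total-count scaling gave 584 up and 897 down, with a median over all genes of -0.03 in place of 0.00, and took Cux2, Rorb, Rasgrf1 and Sgce out of the calls. Without an expression filter Ncor2 reached an adjusted p of 0.0501. Slc17a6 did not pass with total counts (adjusted p = 0.0757), Ptprf did not pass without a filter (0.0515), and neither passed in the joint fit. Without WT libraries 4 and 5, an alternative added after the data were examined, 2750 genes were called.

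Gene length ordered the H3K36me3 changes. The median log2 fold change was -0.03 in genes under 20 kb, -0.01 at 20 to 50 kb, 0.02 at 50 to 100 kb and 0.05 over 100 kb. Among the 2331 genes over 100 kb, 595 (25.5%) rose and 15 (0.644%) fell, whereas 52 genes under 20 kb rose and 254 fell. The length contrast was 3.37 ± 0.04 in WT and 3.45 ± 0.03 in KO (SD, n = 10 each), a difference of 0.07 (two-sided permutation p = 3e-04), and 10 of 10 KO libraries lay above the WT median. The groups overlapped, as WT libraries 4 and 5 (3.439 and 3.437) lay inside the KO range of 3.384 to 3.488. Input libraries differed by 0.00 on the same measure (0.00486, permutation p = 0.61).

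**Figure D1:**
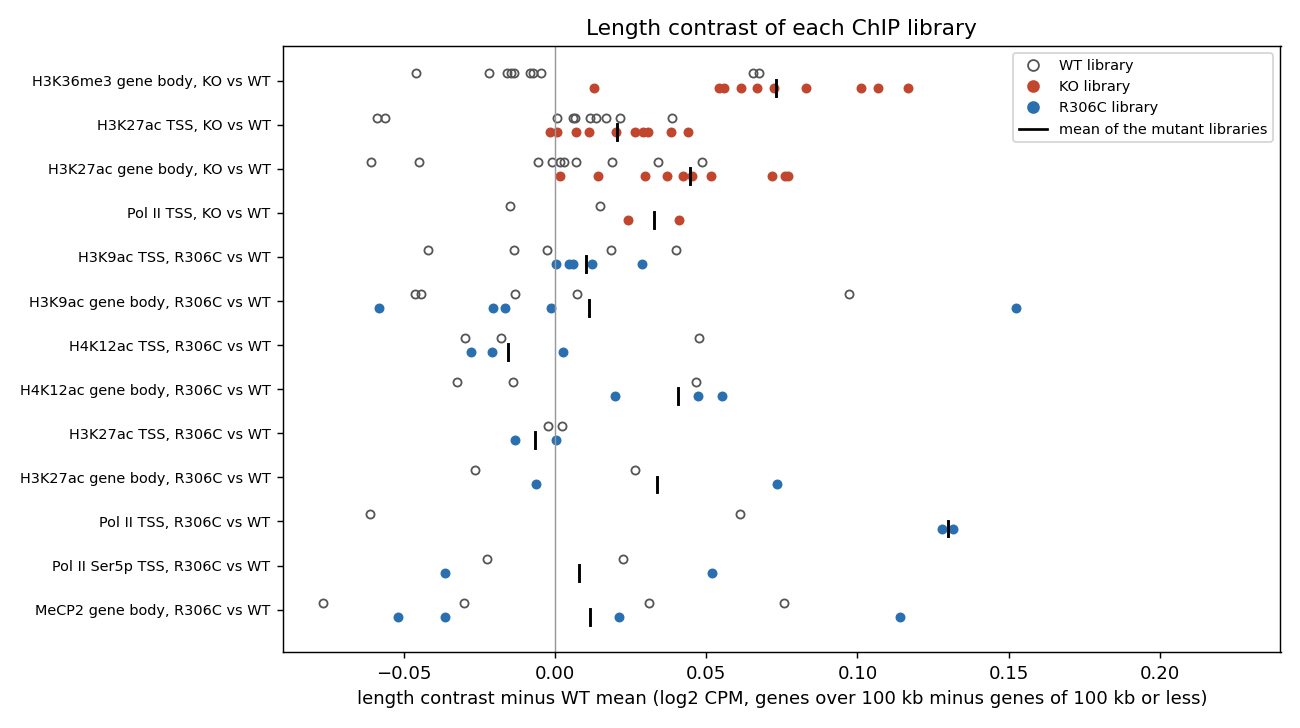
Length contrast of each ChIP library (mean log2 CPM of genes over 100 kb minus that of genes of 100 kb or less) minus the WT mean of its comparison, with open points for WT, filled points for KO or R306C and a bar at the mutant mean. The mutant mean lies at 0.07 for H3K36me3 and at 0.04 for gene body H3K27ac in KO.

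Among called promoters with a mean count of at least 50, H3K27ac in KO fell most at Irak1 (chromosome X, 74013914 to 74023921), from 67.7 to 44.7 CPM (log2 -0.60 ± 0.05 SE, adjusted p = 2.38e-11, n = 10 per group). Other named falls were Stc1, a secreted glycoprotein hormone (-0.51), the growth factor genes Fgf11 (-0.46) and Fgf10 (-0.45), Vwc2, a secreted BMP antagonist (-0.42), and Vcan, a matrix proteoglycan (-0.42). The largest named gains were Filip1l (0.52 ± 0.09, adjusted p = 0.000975), Sipa1l2, a GTPase activator at synapses (0.50), the noncoding RNA gene Nron (0.42) and Dcstamp (0.40). Gm2002 (0.45) and Il11ra2 (0.40) also rose but are near-identical copies whose reads are hard to assign to one of them. In all, 251 of 15175 promoters were called, 134 up and 117 down, with a median size of log2 0.29, and 0 were called in a joint fit with the shallow TSS inputs.

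Glucocorticoid-response genes gained promoter H3K27ac in KO as a list, with 1 up of 13 (6 adjusted over the list alone; median log2 0.09, adjusted p = 0.000737, but adjusted p = 0.18 with an estimated correlation). The called gene was Fkbp5 (0.37, adjusted p = 0.0057), and Zbtb16 (0.25, adjusted p = 0.0681) and Klf9 (0.13, adjusted p = 0.0763), both glucocorticoid-induced transcription factor genes, did not pass over all promoters. Imprinted genes had 3 up of 20 (4 adjusted over the list alone, adjusted p = 0.00918, and adjusted p = 0.0937 with an estimated correlation), which were the growth factor gene Igf2 (0.76, with few counts) and the neighbours Sgce (0.24) and Peg10 (0.23), whose TSS windows overlap. Synaptic adhesion genes had 1 up of 72, Slit1 (0.23, adjusted p = 0.00903), with a median of 0.05 (1 up adjusted over the list alone, list adjusted p = 0.00337, and adjusted p = 0.18 with an estimated correlation). Oxidative phosphorylation genes had 0 of 46 called by edgeR and a median of 0.03 (0 adjusted over the list alone, list adjusted p = 0.0242, and adjusted p = 0.383 with an estimated correlation). Under the DESeq2 Wald test Fkbp5 and Igf2 had adjusted p of 0.0696 and 0.0718, and without WT libraries 4 and 5 Igf2 and Peg10 had 0.0965 and 0.0561. Zbtb16 passed without WT libraries 4 and 5 (0.32, adjusted p = 0.0112) and turned to -0.12 in the joint fit with input. Without WT libraries 6 and 9, which stood apart (first principal component 15.9 and 17.3, and at most 5.66 in the others), all 4 lists passed (adjusted p = 0.00294 each) and Zbtb16 and Klf9 had adjusted p of 0.0941 and 0.139. The astrocyte marker level rose in the same libraries, from 5.64 ± 0.07 to 5.70 ± 0.03 log2 CPM (SD, n = 10 each, permutation p = 0.0267, 9 of 10 KO libraries above the WT median). The length contrast at promoters was 0.32 ± 0.03 in WT and 0.34 ± 0.02 in KO (SD, n = 10 each; difference 0.02, permutation p = 0.086), with 7 of 10 KO libraries above the WT median. It passed with medians (difference 0.03, p = 0.0481) and with active genes only (0.03, p = 0.0074). Without WT libraries 6 and 9, a check added after the data were examined, it was 0.01 (0.00618, permutation p = 0.366).

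In gene bodies, H3K27ac changed at 3627 of 17157 genes in KO, 1837 up and 1790 down, with a median size of log2 0.17. Nmnat3, an enzyme of mitochondrial NAD synthesis (chromosome 9, 98296583 to 98411428), rose from 90.1 to 125 CPM (log2 0.47 ± 0.03 SE, adjusted p = 1.37e-13, n = 10 per group), and Aldh8a1, an aldehyde dehydrogenase gene, rose by log2 0.46. The largest named falls were in the unannotated genes 1700010I02Rik (-0.62) and 4930557F10Rik (-0.60) and in Zfp606, a zinc finger gene (-0.51). 4933407K13Rik rose from 23.0 to 45.6 CPM (0.99 ± 0.04, adjusted p = 8.6e-21), and its input log2 difference in these regions was 0.73. Of the MeCP2-linked genes, Fkbp5 (0.44, adjusted p = 2.4e-06) and Irak1 (0.34) rose and Gabrb3, a GABA receptor subunit gene, fell (-0.15). The joint fit with input called 1424 genes (922 up, 502 down) and no longer called Irak1, and total-count scaling gave 1304 up and 2726 down.

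Synaptic adhesion genes had 29 up and 7 down of 73 in gene body H3K27ac (31 and 7 adjusted over the list alone; median log2 0.06, adjusted p = 7.07e-06, but adjusted p = 0.852 with an estimated correlation). Here too the list gain was not told apart from the trend with gene length. Tenm3 (0.27), the atypical cadherin gene Fat3 (0.28) and the protocadherin genes Pcdh7 (0.27) and Pcdh17 (0.24) rose, while Ptprs, Plxna2, Lingo2, Cdh9, Ncam1, Nfasc and Il1rapl2 fell. Oligodendrocyte markers moved the other way, with 1 up and 5 down of 18 (the same counts adjusted over the list alone; median -0.11, adjusted p = 0.0324, but adjusted p = 0.852 with an estimated correlation). Gpr17, a receptor of oligodendrocyte precursors (-0.32), and the myelin genes Plp1 (-0.24), Ugt8a (-0.17) and Cnp (-0.17) fell, as did Sox10, and Mbp rose by 0.07. In the joint fit with input Gpr17, Plp1, Ugt8a, Cnp, Sox10, Mbp, Ptprs, Lingo2, Cdh9, Ncam1 and Nfasc did not pass. Mbp had an adjusted p of 0.145 with total counts, and Cdh9 had 0.0829 without WT libraries 4 and 5. The mean level of 58 astrocyte, oligodendrocyte, microglia and endothelial markers of 100 kb or less was lower in KO in the gene body H3K27ac libraries. It was 4.46 ± 0.09 log2 CPM in WT and 4.35 ± 0.06 in KO (SD, n = 10 each, permutation p = 0.00483).

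Relative to shorter genes, long genes gained gene body H3K27ac as well. With TMM scaling, 710 (30.5%) of the 2331 genes over 100 kb rose and 379 (16.3%) fell. The median log2 fold change went from -0.03 under 20 kb to 0.02 over 100 kb. The signs depend on the scaling, since total counts gave more falls than rises over all genes. The length contrast compares classes within a library, so it cannot tell a gain at long genes from a loss at shorter ones. The length contrast was 3.75 ± 0.03 in WT and 3.79 ± 0.03 in KO (SD, n = 10 each; difference 0.04, permutation p = 0.00275; 9 of 10 KO libraries above the WT median), and inputs differed by 0.01 (permutation p = 0.54). WT libraries 4 and 5 were again the highest of WT, at 3.796 and 3.782, inside the KO range of 3.749 to 3.825. Adjusting the contrast for the non-neuronal marker level of each library reduced the difference to 0.01 (permutation p = 0.159). That level came from markers of 100 kb or less, the class that the contrast subtracts, so part of the reduction may be built in.

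**Figure D2:**
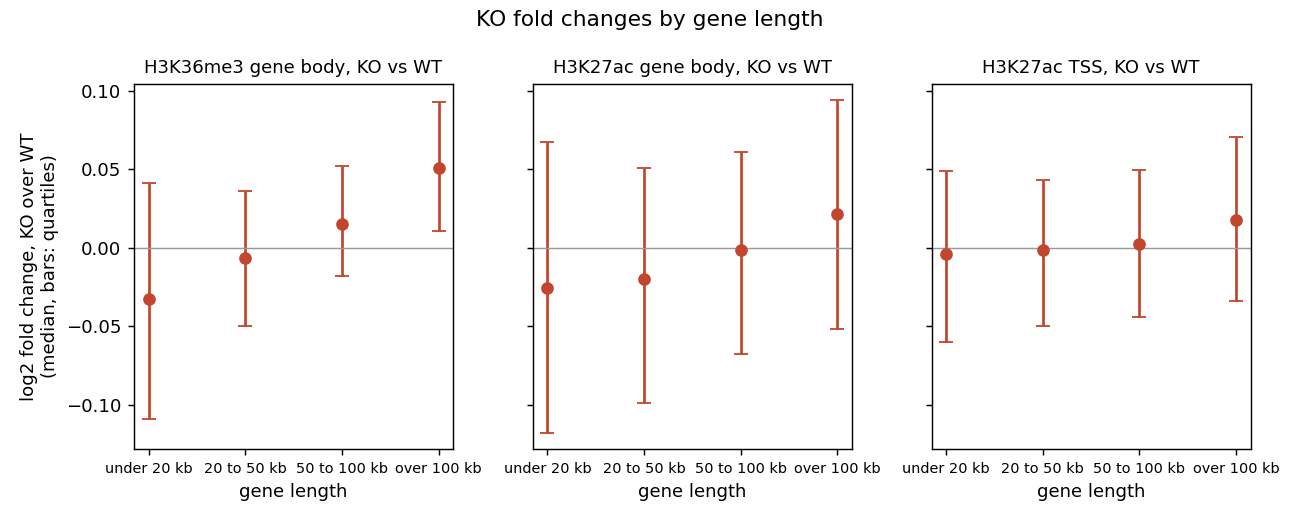
Median log2 fold change (KO over WT) by gene length class for H3K36me3, gene body H3K27ac and promoter H3K27ac, with bars from the lower to the upper quartile over genes. In H3K36me3 the medians go from -0.03 under 20 kb to 0.05 over 100 kb.

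Pol II at the Irak1 promoter fell in KO, from 37.9 to 15.1 CPM (log2 -1.33 ± 0.18 SE, edgeR adjusted p = 2.54e-09, n = 2 per group). The TSS windows of Mir5132 (-1.36) and Mir718 (-1.32) lie on the same stretch, so the 3 calls are 1 signal. The 2 Pol II inputs per genotype read 35.1 ± 0.18 CPM there in WT and 14.3 ± 4.72 in KO (SD; log2 -1.29, edgeR p = 0.0032 but adjusted p = 0.983), and the joint fit with input left Irak1 at -0.03. The inputs of the histone marks of that cohort, with n = 10 per group, differed by less, at 30.9 ± 4.25 and 26.8 ± 7.87 CPM (SD; log2 -0.22, edgeR p = 0.288). Other falls were Ucp2, a mitochondrial uncoupling protein gene (chromosome 7, 100493358 to 100499629; -0.97, adjusted p = 9.73e-06), Fgf11 (-0.96, adjusted p = 0.00159) and Ddr1, a collagen receptor gene (-0.91). Gains included Runx1t1, a transcriptional co-repressor gene (0.54, adjusted p = 0.00248), Reln, the secreted guide of neuronal migration (0.59, adjusted p = 0.0436), and Scn1a, a sodium channel gene (0.58), whose window overlaps that of Gm13629 (0.59). In all, 115 of 21700 promoters were called, 18 up and 97 down, of which 76 of the falls were in genes under 20 kb.

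Glucocorticoid-response genes had less Pol II in KO, with 3 down of 16 (7 adjusted over the list alone; median log2 -0.23, adjusted p = 2.78e-09, but adjusted p = 0.325 with an estimated correlation). These were Zbtb16 (-0.47), the lipid droplet gene Plin4 (-0.74) and Ddit4, an mTOR inhibitor gene (-0.23), whereas the promoter H3K27ac median of the list in KO was positive. Markers of non-neuronal cells were lower as well. Oligodendrocyte markers had 2 down of 20, Mobp (-0.60) and Olig1 (-0.57), with 1 up and 6 down adjusted over the list alone (median -0.37, adjusted p = 1.33e-08, and adjusted p = 0.348 with an estimated correlation). Endothelial and pericyte markers had 2 down of 20, Cldn5, a tight junction gene (-0.80), and Ly6c1 (-0.95), with 3 down adjusted over the list alone (median -0.29, adjusted p = 3.73e-05, and adjusted p = 0.325 with an estimated correlation). Astrocyte markers (median -0.24, adjusted p = 3.04e-06, and adjusted p = 0.367 with an estimated correlation) and microglia markers (median -0.35, adjusted p = 0.000432, and adjusted p = 0.325 with an estimated correlation) had 0 called members in edgeR of 16 and 18 tested. Examples were Gja1 (-0.37) and Hexb (-0.34).

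Some lists of neuronal genes had positive Pol II medians in KO, while inhibitory neuron markers had a negative one that did not pass (-0.10, adjusted p = 0.101). Synaptic adhesion genes (median 0.10, adjusted p = 0.00191, 0 of 71 called by edgeR), ion channels (0.05, adjusted p = 0.0046, 1 up of 43, Scn1a), presynaptic release genes (0.07, adjusted p = 0.0133, 0 of 26) passed, as did silenced developmental genes (0.27, adjusted p = 0.0114, 0 of 13), and activity-induced genes (-0.05, adjusted p = 0.0102, 0 of 32) and MeCP2-linked genes (-0.04, adjusted p = 0.0399, 1 down of 21, Irak1) passed in the other direction. With an estimated correlation their adjusted p were 0.325, 0.325, 0.56, 0.325, 0.603 and 0.348. Adjusted over the list alone, 0, 1 and 0 members of the first 3 lists were up, and 1 activity-induced gene and 4 MeCP2-linked genes were down. The DESeq2 Wald test called 3 promoters, all at the Irak1 stretch, and the joint fit with input called 0.

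Single Pol II libraries decided most KO calls. Without KO library 2, 15 promoters were called, and Ucp2 (-0.58, adjusted p = 0.462), Fgf11 (-0.78, 0.372), Zbtb16 (-0.24, 0.941), Plin4 (-0.54, 0.694), Mobp (-0.45, 0.608), Olig1 (-0.43, 0.754), Cldn5 (-0.65, 0.449) and Ly6c1 (-0.71, 0.759) no longer passed in edgeR. Without WT library 2, 26 were called and Plin4 was at -0.29 (adjusted p = 0.938) and Zbtb16 at -0.44 (0.115), with Mobp, Olig1, Cldn5 and Ly6c1 at adjusted p of 0.522, 0.476, 0.0773 and 0.732. Fgf11 had 0.0557 without WT library 1. Reln was at 0.40 (adjusted p = 0.532) without WT library 1 and at 0.08 (0.0829, adjusted p = 0.987) without KO library 2, and with total counts its adjusted p was 0.125. Scn1a had 0.262, 0.0967, 0.216 and 0.329 without WT library 1, WT library 2, KO library 1 and KO library 2. Ddr1 had 0.0692, 0.0833 and 0.499 without WT library 1, WT library 2 and KO library 2, and Ddit4 had 0.513, 0.152 and 0.363 without WT library 2, KO library 1 and KO library 2. Runx1t1 had adjusted p of 0.145, 0.0865 and 0.0807 without WT library 1, KO library 1 and KO library 2. Irak1 passed without any single library. The length contrast was 0.49 ± 0.02 in WT and 0.52 ± 0.01 in KO (SD, n = 2; difference 0.03, exact permutation p = 0.333, the smallest possible), and that of the inputs also differed by 0.03.

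The R306C cohort asks the same of an allele that leaves MeCP2 protein present. H3K9ac at the TSS fell at Cacnb3 (chromosome 15, 98632328 to 98644536) and Cacna1g, which encode a calcium channel beta subunit and a T-type calcium channel (log2 -0.61 ± 0.10 and -0.40 ± 0.06 SE, both edgeR adjusted p = 0.0108, n = 5), and at Fgf11 (-0.42 ± 0.08, adjusted p = 0.0371), and rose at Trabd2b, a Wnt-processing protease gene (0.39 ± 0.07, adjusted p = 0.0371). With genotype as the only term, edgeR called these 4 of 16381 promoters. No call was left without WT library 1, WT library 5 or R306C library 5 (edgeR 0), and 1 was left without R306C library 2 and 2 without WT library 2, 3 or 4. DESeq2 called 2 (Trabd2b and Fgf11 had adjusted p of 0.0583), and the joint fit with input called 0. A block for the replicate number called more promoters. Residuals of same-numbered libraries had a median correlation of 0.276, against -0.0396 for other numbers, so the count depends on leaving that number out. In gene bodies the same fit called 1 of 17694 genes for H3K9ac, 4933407K13Rik (20.6 to 37.1 CPM, log2 0.85 ± 0.07, edgeR adjusted p = 2.05e-06, n = 5), whose input log2 difference was 0.70. The joint fit with input did not call it, and DESeq2 called 19 genes. Without WT library 5, 2 genes were called. The block for the replicate number called more genes here too (median correlation 0.509 for the same number, against -0.0549 for others). Oligodendrocyte markers had 0 of 18 called in edgeR and a median of -0.07 (list adjusted p = 0.00688, 0 adjusted over the list alone, and adjusted p = 0.957 with an estimated correlation). Pdgfra, the growth factor receptor of their precursors, was at -0.22 and Sox10 at -0.27.

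H4K12ac in R306C had 0 calls at 17243 promoters in edgeR and in DESeq2, with 781 promoters at an unadjusted p under 0.05, and 0 lists passed. The smallest p belonged to Vwce (log2 -0.76, edgeR adjusted p = 0.118, n = 3), and Wnt4, a secreted Wnt ligand, was at -0.59 and Stx8, an endosomal SNARE, at 0.53. In gene bodies the fit with genotype as the only term called 1 of 17821 genes, again 4933407K13Rik (19.2 to 32.5 CPM, 0.76 ± 0.09 SE, edgeR adjusted p = 0.0212, n = 3), which was not called in the joint fit with input nor without WT library 2, R306C library 2 or R306C library 3 (0 calls each), and 2 genes were called without WT library 3. A block for the replicate number called more genes in these bodies (median correlation 0.350 for the same number, against -0.168 for others). Synaptic adhesion genes had a positive median of 0.04 (adjusted p = 2.73e-06, 0 of 73 called by edgeR, and adjusted p = 0.936 with an estimated correlation). Tenm3 was at 0.18 and Fat3 at 0.15. Presynaptic release genes had a median of -0.06 (adjusted p = 0.00288, 0 of 24 called by edgeR, and adjusted p = 0.936 with an estimated correlation). The SNARE gene Stx1b was at -0.25 and the dynamin gene Dnm1 at -0.17. Adjusted over the list alone, 0 members of either list passed in edgeR.

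H3K27ac at R306C promoters fell at Btaf1 (chromosome 19, 36926079 to 37014057), which encodes a remover of TATA-binding protein, from 209 to 146 CPM (log2 -0.51 ± 0.07 SE, edgeR adjusted p = 0.0364, n = 2). That was the 1 call of 15193 promoters. It was lost in the joint fit with input and without WT library 4 (0 calls). The count was 2 without WT library 5, 9 without R306C library 4 and 70 without R306C library 5. In gene bodies edgeR called 0 of 17197 genes (756 at an unadjusted p under 0.05) and DESeq2 called 1, and edgeR called 2164 without R306C library 5 and 163 without R306C library 4. The smallest p belonged to 4933407K13Rik (0.88, adjusted p = 0.5681) and Pisd-ps1, a pseudogene (-0.84, adjusted p = 0.602), followed by Esrrg, a nuclear receptor gene (0.47). All 3 passed in edgeR without R306C library 4 (0.97, -0.89 and 0.42) and without R306C library 5 (0.78, -0.80 and 0.52), and the 1 gene called by DESeq2 was 4933407K13Rik (adjusted p = 0.0497). Oligodendrocyte markers had a median of -0.21 (adjusted p = 0.00109, and adjusted p = 0.766 with an estimated correlation), synaptic adhesion genes 0.09 (adjusted p = 0.00137, and adjusted p = 0.766 with an estimated correlation) and silenced developmental genes 0.30 (adjusted p = 0.00186, and adjusted p = 0.766 with an estimated correlation). Of these lists 0 members passed in edgeR, adjusted over the list alone or not, and Gpr17 was at -0.35, Tenm3 at 0.25 and Pax5 at 0.28. R306C library 4 stood apart, with a first principal component of 21.9 against -10.6 to -2.65 in the other 3 libraries. Without R306C library 5, which leaves R306C library 4 alone, these genes passed in edgeR, at -0.66 (adjusted p = 0.00394), 0.32 (0.00549) and 0.30 (0.0405). Without R306C library 4 they were at -0.09 (-0.0922, adjusted p = 0.889), 0.17 (0.413) and 0.26 (0.243).

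Pol II at R306C promoters had 0 calls of 22516 in edgeR and in DESeq2, with 949 at an unadjusted p under 0.05. Without WT library 2, 602 were called, and without WT library 1, 58. The smallest p belonged to the overlapping windows of Nt5c2 (0.51, adjusted p = 0.997) and Ina (0.49), and Mast4, a kinase gene, was at 0.61. Nt5c2 and Ina passed without WT library 2 (adjusted p = 0.00459 and 0.0107) and without WT library 1 (0.0452 and 0.0442). WT library 1 stood apart, with a first principal component of -22.2 against 2.63 to 13.4 in the other 3 libraries and a length contrast of 0.37 against 0.49 to 0.56. Several lists had positive medians, though 0 passed with an estimated correlation. They were activity-induced genes (0.11, adjusted p = 0.000272, with Arc at 0.39 and Fosb at 0.52), presynaptic release genes (0.13, adjusted p = 0.000272), ion channels (0.12, adjusted p = 0.00153), the MeCP2 and NCoR complex (0.17, adjusted p = 0.00153, with Tet2 at 0.37), synaptic adhesion genes (0.10, adjusted p = 0.00712, with Robo1 at 0.60) and inhibitory neuron markers (0.17, adjusted p = 0.019, with Slc32a1, the vesicular GABA transporter gene, at 0.54). Without WT library 2, Arc (0.52, adjusted p = 0.00558), Fosb (0.70, 0.0267), Tet2 (0.64, 0.00349) and Robo1 (0.83, 0.0284) passed against WT library 1 alone. Without WT library 1 they were at 0.29 (adjusted p = 0.518), 0.39 (0.656), 0.18 (0.858) and 0.42 (0.691). Endothelial markers (-0.41, adjusted p = 0.00181) and liver, muscle and blood genes (-0.26, adjusted p = 0.00351, with albumin, Alb, at -1.10) had negative medians. With an estimated correlation the adjusted p of these 8 lists were 0.539, 0.414, 0.414, 0.437, 0.414, 0.414, 0.65 and 0.414, and 0 members passed in edgeR, adjusted over the list alone or not. Ser5p had 0 calls of 22201 in edgeR and in DESeq2, with 814 at an unadjusted p under 0.05, against 42 without WT library 1 and 2 without R306C library 1. Ribosomal protein genes had a median Ser5p change of -0.12 (adjusted p = 1.3e-06, 0 of 76 called by edgeR, and adjusted p = 0.938 with an estimated correlation), with Rps23 at -0.52 and Rplp0 at -0.35, and 0 passed adjusted over the list alone.

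The length contrast did not pass in any R306C comparison, but groups of 2 or 3 libraries could not reach 0.05 in this test (smallest p 0.333 and 0.1). The difference of the length contrast between R306C and WT was 0.01 for H3K9ac at the TSS (exact permutation p = 0.516, n = 5) and 0.01 in gene bodies (p = 0.762), -0.02 and 0.04 for H4K12ac (exact p = 0.7 and 0.2, n = 3), -0.01 and 0.03 for H3K27ac (exact p = 0.667 for both, n = 2), 0.13 for Pol II (exact p = 0.333, the smallest possible with n = 2), 0.01 for Ser5p (exact p = 1, n = 2) and 0.01 for MeCP2 (exact p = 0.83, n = 4). In Pol II 2 of 2 R306C libraries lay above the WT median, and the difference was 0.07 (0.0686) to 0.19 with 1 library left out. In H4K12ac bodies 3 of 3 did, and the difference was 0.02 (0.0244) to 0.06 (0.0641) with 1 left out. The H3K9ac gene body difference was -0.02 without R306C library 4, -0.000522 without WT library 2 and -6.08e-05 without WT library 1, and the TSS difference was -0.000255 without WT library 2. The H4K12ac TSS difference was 0.01 (0.00837) without WT library 3, the H3K27ac differences were 0.000199 at the TSS and -0.01 (-0.00618) in gene bodies without R306C library 4, and the Ser5p difference was -0.01 (-0.0148) without WT library 1 and -0.04 without R306C library 1. The MeCP2 difference was -0.01 without WT library 1 and -0.02 without R306C library 3.

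Promoters called for H3K27ac in KO were read in the R306C libraries. Of 250 such promoters measured in both, 232 (92.8%) had the same sign in H3K27ac of R306C, against 7.6% to 56.4% in the 5 other assignments of the R306C cohort's libraries, which are too few for a test. The correlation across genes was 0.263 (p = 0.0099 from redrawn KO genotypes, the smallest that 100 draws give, adjusted p = 0.0488). For H3K9ac of R306C, 227 of 250 (90.8%) had the same sign and the correlation was 0.292 (permutation p = 0.0099, adjusted p = 0.0488). In 1 of 100 redrawn assignments of the R306C cohort's libraries the share reached 91.6%. These draws could repeat the real assignment. Their highest correlation of H3K9ac with promoter H3K27ac of R306C matched the real one (0.227). The 91.6% may thus come from the real assignment and not from a regrouping. Correlations of promoter H3K27ac in KO with promoter H4K12ac (0.122, adjusted p = 0.224), Pol II (0.138, adjusted p = 0.617) and Ser5p (0.0466, adjusted p = 0.617) of R306C did not pass. All 4 promoters called for H3K9ac in R306C were also called for H3K27ac in KO, with the same sign. In gene bodies, H3K27ac of KO and H3K9ac of R306C correlated at 0.439 (permutation p = 0.0099, adjusted p = 0.0488), with 3138 of 3625 called genes (86.6%) sharing the sign, and H3K27ac of both alleles at 0.291 (p = 0.0594, adjusted p = 0.169). Within KO, H3K36me3 correlated with promoter H3K27ac at 0.279 (permutation p = 0.0099, adjusted p = 0.0488; 77 of 78 genes called in both shared the sign), with gene body H3K27ac at 0.252 (p = 0.0198, adjusted p = 0.0666; 645 of 665) and promoter H3K27ac with Pol II at 0.175 (p = 0.0198, adjusted p = 0.0666; 12 of 12). Pol II of both alleles correlated at 0.0983 (permutation p = 0.333). These correlations are across genes, which are not independent replicates.

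**Figure D3:**
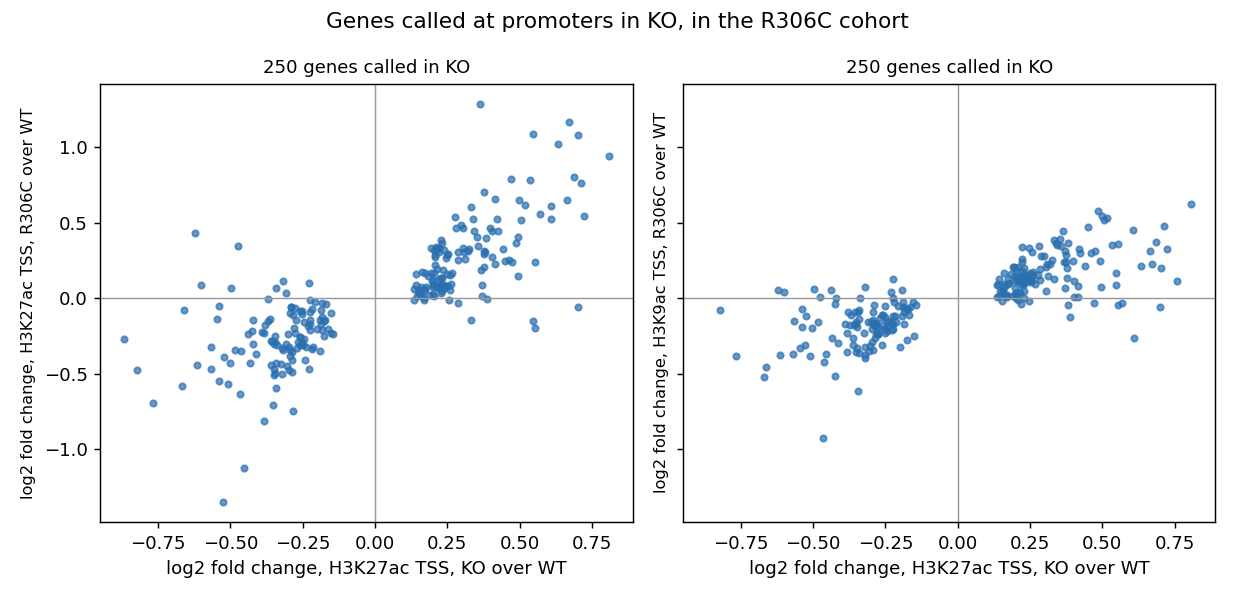
Log2 fold change at promoters called for H3K27ac in KO (horizontal axis) against that in R306C (vertical axis) for H3K27ac and for H3K9ac, with a point per promoter. Of 250 promoters, 232 share the sign for H3K27ac and 227 for H3K9ac.

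The direct test of KO against R306C found 2 promoters of 16272 with different H3K27ac effects. Irak1 was 0.68 ± 0.12 higher in R306C than in KO on the log2 scale (SE, edgeR adjusted p = 0.00506), and Btaf1 was -0.53 ± 0.09 lower (adjusted p = 0.00344). For Pol II 0 of 23526 promoters differed in edgeR (875 at an unadjusted p under 0.05, smallest adjusted p = 0.212). These tests compare 2 cohorts, so allele and cohort cannot be told apart in them.

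MeCP2 ChIP in WT lay far above input in the bodies of few genes. Ratios were scaled by library totals, so broad binding cannot be told apart from weak enrichment over input here. Of 17814 genes, 2542 were higher than input and 4123 lower, and 8 (0.0449%) exceeded a log2 ratio of 1. High ratios were found at P2ry1, a purinergic receptor gene (chromosome 3, 61002785 to 61008982; 1.03 ± 0.18 SE, edgeR adjusted p = 2.39e-05, n = 4), Cbln2, a synaptic organiser gene (1.00), Fgf5 (0.92), the Polycomb gene Bmi1 (0.92) and C1ql3 (0.92), and at Dhrsx (1.21), which lies on an unplaced contig. Excitatory neuron markers had a median ratio of 0.18, oxidative phosphorylation genes -0.27 and proteasome genes -0.34. The class medians were -0.07, -0.08, -0.02 and 0.04 from the shortest to the longest genes. The length contrast of ChIP was 0.09 above that of input in WT (exact permutation p = 0.0571, n = 4, with 0.0286 the smallest possible), and 0.12 without WT ChIP library 1 (p = 0.0286), and it was 0.10 above input in R306C (exact p = 0.0857). ChIP columns lay above the input column of the same number in 4 of 4 cases in WT (by 0.05 to 0.13) and 4 of 4 in R306C (by 0.07 to 0.14). The labels tie these input columns to other numbers, so the columns were not tested as pairs.

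R306C and WT did not differ detectably in MeCP2 at single genes, with 0 of 17775 called in edgeR and in DESeq2 and 427 at an unadjusted p under 0.05. Without R306C library 3, 16 were called, and without WT library 1, 1 was. The smallest p belonged to 4933407K13Rik (9.11 to 15.1 CPM, log2 0.73 ± 0.13 SE, edgeR adjusted p = 0.0923, n = 4), which also differed in the inputs by 0.68 and passed without R306C library 3 (0.77, adjusted p = 0.0127) and without WT library 1 (0.81, adjusted p = 0.0365). Lrrc2 was at 0.27, Cpne7 at -0.36 and Irak1 at -0.52. No list passed.

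**Figure D4:**
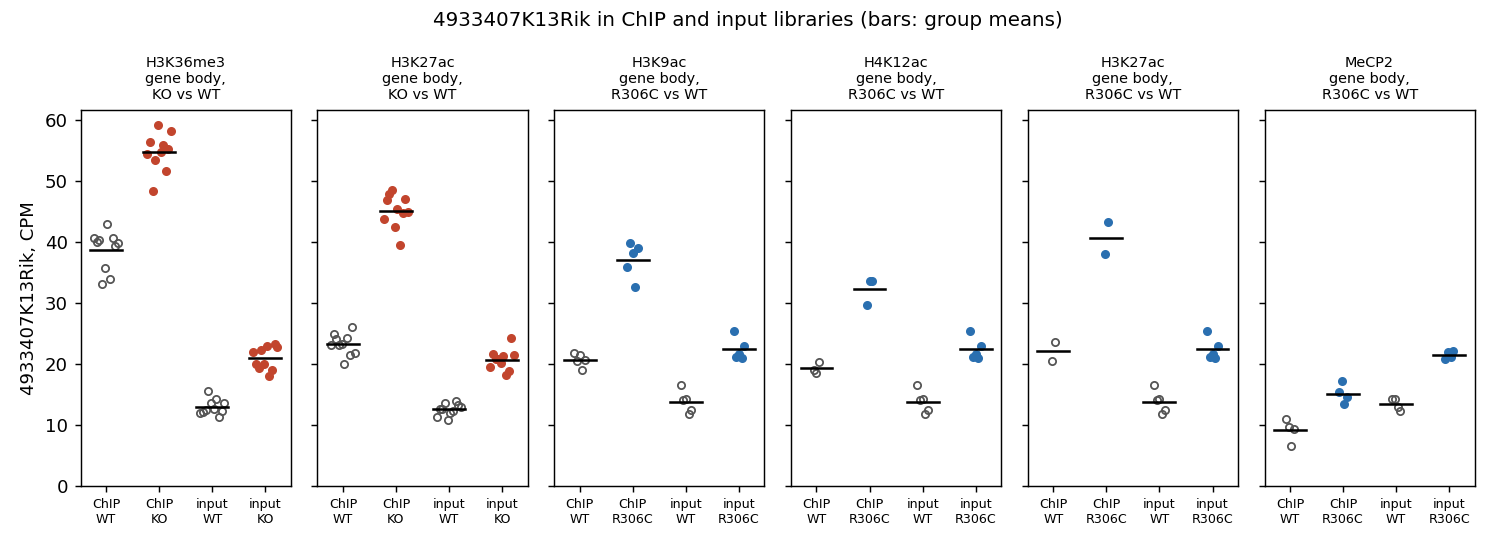
CPM of 4933407K13Rik in each ChIP and input library of 6 gene body comparisons, with a point per library and bars at group means. Mutant ChIP and input libraries lie above those of WT in each comparison shown.

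H3K79me2, a mark of early elongation, was above input by more than log2 1 at 1113 of 23041 genes in WT (4.83%). Ywhae, a 14-3-3 adaptor gene (chromosome 11, 75732887 to 75765841), read 138 CPM against 39.1 in input (log2 1.83 ± 0.06 SE, n = 2), and Ski (1.81), Rbm12 (1.79) and the chromatin regulator gene Ankrd11 (1.78) were also among the highest. MeCP2 and NCoR complex genes had 6 of 20 members above the threshold (median 0.69) and oxidative phosphorylation genes 12 of 65 (median 0.42), whereas silenced developmental genes had 0 of 44 (median -2.92) and microglia markers a median of -1.64. Genes of 50 to 100 kb were above the threshold most often (12.4%), against 2.06% under 20 kb, 6.93% at 20 to 50 kb and 7.76% over 100 kb. With TMM in place of total counts 5526 genes were above it.

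YY1 motifs within YY1 peaks of cultured neurons numbered 18709, each 12 bp long, on 21 chromosomes. Of these, 3872 (20.7%) lay within 1 kb of a TSS, and 3862 of 24498 genes (15.8%) had one. Genes of basic metabolism had the largest shares, with 42 of 65 oxidative phosphorylation genes (64.6%), 42 of 76 ribosomal protein genes (55.3%) and 17 of 31 proteasome genes (54.8%), against 6 of 73 synaptic adhesion genes (8.22%) and 0 of 18 microglia markers. No test against other lists was run.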

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

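Tests of DNA reads over 4933407K13Rik, of input subtraction and oligodendrocyte markers in the length contrast, and of non-neuronal markers in Pol II and H3K27ac of KO were chosen only after the result was seen.

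Counts over 4933407K13Rik, a chromosome X gene and the only gene called in inputs, differed with genotype in input DNA, which no comparison of the report was built on. The input log2 difference was 0.69 over whole genes and 0.73 over bodies from 3 kb in KO, and 0.70 and 0.68 in the 2 R306C input sets, so more DNA reads over the locus may account for most of its gain, while H3K27ac in KO rose by 0.27 beyond the DNA difference (SE 0.07, edgeR p = 0.000307). For Irak1, fewer DNA reads over the promoter in KO cannot be told apart from a loss of H3K27ac, since the interaction with input was -0.38 (SE 0.20, p = 0.067) on few input counts. In the inputs of the histone marks the change alone was -0.22 (SE 0.20, edgeR p = 0.288) at the promoter, against -0.60 in H3K27ac ChIP. Over the whole gene it was 0.25 (edgeR p = 0.0381, adjusted p = 0.988). The Pol II inputs, with 2 libraries per genotype, differed by more at the promoter, at 35.1 CPM in WT and 14.3 in KO (log2 -1.29). Pol II ChIP changed there by -1.33, so the input sets of the KO cohort differ in how far fewer DNA reads could account for the falls. Variation linked to the targeted allele cannot be told apart from other sources of the calls near Mecp2, since few genes lie within 10 Mb of it. Called there were 1 of 69 promoters for H3K27ac (1.45% against 1.66% elsewhere, Fisher's exact p = 1), 12 of 104 genes for H3K36me3 (against 7.46% elsewhere, p = 0.131), 13 of 82 for gene body H3K27ac (15.9% against 21.2%, p = 0.279) and 3 of 88 promoters for Pol II (3.41% against 0.518%). The 3 overlap at Irak1, and with overlapping windows merged 1 of 75 stretches was called for Pol II (1.33% against 0.475%, p = 0.303). A copy-number or strain difference at the locus itself was not tested.

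Long genes gained H3K36me3 and gene body H3K27ac in KO relative to shorter genes. Input DNA that differs with gene length is argued against, since the difference after subtracting matched inputs was 0.07 (0.0684, permutation p = 0.00082) for H3K36me3 and 0.04 (0.0393, p = 0.008) for H3K27ac, as is a difference in ChIP enrichment, with adjusted differences of 0.06 (0.0648, p = 7e-05) and 0.04 (0.0424, p = 0.00374). For H3K27ac the enrichment index hardly tracked the contrast within groups (correlation 0.0895), with a slope of 0.03 (0.0291, SE 0.0785) where 0.574 would be needed to give the whole difference. For H3K36me3, oligodendrocyte markers were lower in KO too, and adjustment for their level left a difference of 0.06 (0.0603, p = 0.0015), and adjustment for the level of all 4 non-neuronal lists left 0.0655 (p = 0.00064). These values argue against a differing share of such cells as the whole cause, though both levels tracked the contrast weakly within groups (correlations -0.227 and -0.311), so a part stays open. For H3K27ac an equal fall of all 4 non-neuronal list levels is argued against, since astrocyte markers parted from the other 3 lists in 10 of 10 KO libraries (0.11, permutation p = 0.00244). Lists may differ in background reads, so this does not decide how the cell shares changed. A lower share of oligodendrocytes, microglia and endothelial cells may account for some of the gain. Adjustment for oligodendrocyte markers left 0.0118 (permutation p = 0.221). Adjustment for the level of all 4 lists took the difference from 0.0447 to 0.0136 (permutation p = 0.159). The pooled SD went from 0.0294 to 0.0207, so the call ended because the difference shrank. For both marks, the levels used to adjust came from markers of 100 kb or less, the class that the contrast subtracts. Part of the shrinkage may thus be built in, and the adjustment cannot settle this cause. A direct effect of MeCP2 loss on long genes stays open as a hypothesis for both marks.

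Markers of 4 non-neuronal cell types were all lower at Pol II promoters in KO. A lower share of non-neuronal cells in the 2 KO libraries cannot be told apart from lower Pol II at these genes within cells. With 2 libraries per group, the test of whether astrocyte markers part from the other 3 lists (0.06, 0.06445, exact permutation p = 0.333) cannot give a smaller p. An equal fall of all 4 list levels in the other KO libraries is argued against by promoter H3K27ac. There the astrocyte level minus the mean of the other 3 lists rose by 0.11 in KO (0.1094, permutation p = 0.0224, above the WT median in 9 of 10 KO libraries). Without WT libraries 6 and 9, median log2 fold changes were 0.052 for astrocyte, -0.00433 for endothelial, -0.0196 for microglia and -0.00502 for oligodendrocyte markers. The level test was not rerun without them. Lists may differ in background reads, so list levels do not decide how cell shares changed. A lower share of the other 3 types stays open there. A fall of all promoters of like abundance is argued against too, as the list medians lay at or below the 0.31 percentile of matched lists.

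A library stood apart from its group in 11 of 246 tests (4.47%). Each test took 1 measure in 1 group, which was the length contrast, the library total or the CPM of a named gene. Chance alone gives about 1 in 20, but these tests share libraries and are not independent. In H3K36me3, WT library 4 read 314 CPM at Cux1 against 323 to 332 in the other WT libraries and 269 CPM at Kcnd2 against 206 to 239. WT library 2 read 138 CPM at Grik3 against 151 to 163. KO library 3 read 8.08 CPM at Zfp616 against 5.42 to 6.46 in the other KO libraries, and KO library 2 read 193 CPM (192.5) at Kcnh5 against 212 to 233. Promoter H3K27ac of Fgf10 was 35.4 CPM in WT library 9 against 23.0 to 29.2 in the others. Gene body H3K27ac of Fkbp5 was 140.0 CPM in WT library 5 against 82.8 to 112. The H3K9ac gene body length contrast of R306C library 4 was 3.69 against 3.48 to 3.53. WT input library 4 of the KO cohort had a TSS length contrast of 0.0422 against -0.0573 to -0.00675 and a total of 429700 counts against 325200 to 355500, and WT input library 4 of the R306C cohort held 9207000 gene body counts against 8783000 to 8879000. The H3K27ac effect of R306C minus that of KO was -0.53 at Btaf1 and 0.68 at Irak1, both past an interaction test between cohorts.

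Other splits of the libraries into groups of the same sizes were counted for each comparison with at least 3 libraries per group. In KO, 100 of the 92378 possible splits were counted, the real one among them. None of the others drawn reached the real count. For H3K36me3 the real count was 1483 and the highest other 1, for promoter H3K27ac 251 and 166, and for gene body H3K27ac 3627 and 537. Chance is thus argued against for these libraries, as far as the splits drawn show. Chance cannot be excluded in R306C for H3K9ac at the TSS, where the real count was 4, 7 of 100 splits reached as many and the highest other gave 280. Nor can it in gene bodies (real count 1, 8 of 100, highest other 1653). Splits that call so many more genes point to a structure of the samples other than genotype. The splits did not use the replicate number, and a block for it called more H3K9ac genes in both regions. With 3 libraries per group there are 10 splits, too few for a share under 0.05. For H4K12ac in gene bodies the real count was 1, 3 of 10 splits reached it and the highest other was 527. A real count of 0 is reached by any split, so the splits decide nothing for H4K12ac at the TSS (10 of 10, highest other 1) and for MeCP2 in R306C (35 of 35, highest other 631), though the last value points to a structure of the samples other than genotype.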

How the results depend on the processing

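Fits without WT libraries 4 and 5 or 6 and 9 of the KO cohort were chosen only after the data were examined. So was the use of input subtraction to weigh a cause of the length contrast. All other settings were chosen before. In all, 229 results were recomputed in 1912 alternatives, of which 1585 held. Tested values held if they kept direction and side of the threshold, or stayed within the spread where groups were small. Counts of genes and lists held if they stayed within a fixed factor of the main count. Unless the setting's construction shows it, the cause of a change was not tested. Of 1560 alternative values for 177 named gene results, 1301 held, 220 lost the call (88 in the joint fit with input, 79 with 1 library left out, 24 under DESeq2, 11 with total counts, 9 with the replicate block, 5 with no filter and 4 without WT libraries 4 and 5) and 16 turned direction. The joint fit with input, which adds the noise of the input counts, called 274 genes for H3K36me3 and 1424 for gene body H3K27ac in KO, and 0 for promoter H3K27ac and Pol II in KO, for H3K9ac in either region, for gene body H4K12ac and for promoter H3K27ac in R306C. In that fit 4933407K13Rik (-0.16, -0.1637) and Irak1 (-0.03, -0.02873) turned in H3K36me3, Zbtb16 (-0.12) in promoter H3K27ac, Mir718 (0.02435) and Mecp2 (-0.16, -0.1568) in Pol II of KO, and Mecp2 in Pol II of R306C (-0.10) and in MeCP2 ChIP (0.06179). Mecp2 in promoter H3K27ac of R306C turned with no filter (-0.01, -0.01474) and in DESeq2 (-0.01, -0.007076). DESeq2 called 3 promoters for Pol II in KO, 2 for H3K9ac at the TSS, 19 in H3K9ac bodies and 1 in H3K27ac bodies of R306C. Without WT libraries 4 and 5, 2750 genes were called for H3K36me3. With TMM, 5526 genes were above the H3K79me2 threshold. Lists past the threshold fell from 7 (H3K36me3), 4 (promoter H3K27ac), 2 (gene body H3K27ac), 11 (Pol II), 1 (H3K9ac bodies), 2 (H4K12ac bodies), 3 (H3K27ac bodies), 8 (Pol II of R306C) and 1 (Ser5p) to 0 in each with an estimated correlation. Without WT libraries 6 and 9, 6 lists passed for promoter H3K27ac. The length contrast of promoter H3K27ac in KO passed with medians (0.02956) and active genes only (0.02705). Differences of other length contrasts that moved were 0.1353 with medians and 0.001068 after input subtraction for Pol II in KO, -0.03196 with no filter and 0.00808 with active genes for promoter H3K27ac of R306C, and 0.05841 with medians for Ser5p. With 1 library left out, counts ranged from 15 to 125 for Pol II in KO, 0 to 6 and 1 to 2 for H3K9ac, 0 to 0 and 0 to 2 for H4K12ac, 0 to 70 and 0 to 2164 for H3K27ac of R306C, 0 to 602 for its Pol II, 0 to 42 for Ser5p, 0 to 16 for MeCP2 and 998 to 1222 for H3K79me2. Length contrast differences ranged from -0.0002548 to 0.02029 and -0.0243 to 0.03535 for H3K9ac, -0.03035 to 0.008366 and 0.02442 to 0.06405 for H4K12ac, -0.0133 to 0.000199 and -0.006175 to 0.07341 for H3K27ac of R306C, -0.03643 to 0.05186 for Ser5p, 0.0686 to 0.1912 for Pol II of R306C, 0.01773 to 0.04739 for Pol II of KO, -0.02244 to 0.03689 for MeCP2, and 0.06455 to 0.1155 for MeCP2 against input. Mecp2, uncalled in these tables, ranged from -0.04752 to 0.1899 in Pol II of KO, -0.0616 to 0.05866 and -0.2859 to 0.03271 in promoter and gene body H3K27ac of R306C, and -0.1221 to 0.05718 in MeCP2 ChIP. Where a group was left with 1 library, that library was assumed to vary like the others. The labels do not say what the replicate numbers mark, and in none of the comparisons were all WT and mutant residuals with the same number correlated above 0.1. These correlations ran from -0.223 to 0.278 in H3K36me3, -0.207 to 0.284 and -0.169 to 0.152 in H3K27ac of KO, 0.0551 to 0.394 and 0.00609 to 0.539 in H3K9ac, 0.0217 to 0.059 and -0.0507 to 0.463 in H4K12ac and -0.00128 to 0.354 in MeCP2, and were -0.0255 for Pol II in KO, -0.105 for Pol II and -0.0619 for Ser5p in R306C. In H3K9ac the median was 0.276 at the TSS and 0.509 in gene bodies for the same number, against -0.0396 and -0.0549 for other numbers, and 3 and 4 of 5 libraries correlated best with their own number. In H4K12ac bodies it was 0.350 against -0.168, with 2 of 3. These are hints from the data that some same-numbered libraries share a structure. A block for that number gave 54 promoters for Pol II in KO, 31 and 75 genes for H3K9ac, 47 for H4K12ac bodies and 2 lists for H3K9ac bodies. No paired analysis was run for H3K27ac of R306C. Its columns carry the numbers 4 and 5 in both genotypes, but the titles carry other numbers. Input subtraction was not run for MeCP2, H3K27ac or H4K12ac of R306C. Their column numbers recur among the input columns, but the labels do not say that these share animals. For MeCP2 the labels tie the input columns to other numbers. Depth limits the TSS inputs, at 0.323 to 0.548 megacounts, and groups of 2.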

Other observations

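In H3K36me3 of KO, 7 of 20 lists passed. Among the others, inhibitory neuron markers had 2 up of 21 (median log2 0.03, adjusted p = 0.0962), presynaptic release genes 1 up of 26 (0.04, adjusted p = 0.0996), glucocorticoid-response genes 4 up of 16 (0.02, adjusted p = 0.0569) and oxidative phosphorylation genes 0 of 64 in edgeR (-0.02, adjusted p = 0.288). Liver, muscle and blood genes (median 0.05, adjusted p = 0.627), silenced developmental genes (-0.07, adjusted p = 0.372) and activity-induced genes (0.01, adjusted p = 0.366) did not pass either.

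A hypothesis set before its test holds that long genes with more MeCP2 in WT gain more of each mark in KO. Across the 2331 genes over 100 kb, the MeCP2 ratio to input in WT correlated with the KO change, as the hypothesis predicts. The correlation was 0.497 for H3K36me3 (permutation p = 0.0433) and 0.49 for gene body H3K27ac (permutation p = 0.0284). The central 95% of permuted values ran from -0.49 to 0.486 and from -0.473 to 0.473, so both lay only just outside. Regrouped libraries thus gave correlations nearly as large. The same correlation over genes of 100 kb or less was 0.263 (p = 0.0085) and 0.257 (p = 7e-04), so it is not a property of long genes alone, and a shared dependence of both measures on base composition could not be tested without a genome sequence. Genes are not independent replicates, and permutations were of KO and WT libraries.

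A second hypothesis, also set before its test, was that promoters with a YY1 motif in cultured neurons change in H3K27ac in KO. Promoters with a motif (3317) and without (11858) differed by 1.07 ± 0.03 log2 CPM in WT and 1.07 ± 0.02 in KO (SD, n = 10 each), a change of -0.00211 (permutation p = 0.874), so no shift was detected.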
